A study of Mus musculus with 64 samples.

How the data were processed

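RNA was sequenced from V6.5 mouse embryonic stem cells, wild type or with a degron on 1 of the 12 Pol II subunits. Per the labels' protocols, the medium held CHIR99021 and PD0325901, inhibitors of GSK3 and MEK, doxycycline at 2 µg/ml for 12 h induced the auxin receptor protein OsTir1, and IAA at 500 µM then triggered degradation. The series text gives 1 µg/ml of doxycycline. Drosophila S2 cells were added at 10% as a spike-in before extraction. The protocol names poly(A) libraries for the 12 h samples; the library type of the 0 h and 1 h samples is not given in the sources used here, so those 12 libraries were fitted apart. Whether wild-type cells carried OsTir1 is not given either.

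The authors deposited 1 table of raw counts per gene and library, whole numbers for 55335 Ensembl mouse genes. Per the submitters' processing notes, which give no role or order, cutadapt 1.18, Bowtie2, STAR, SAMtools, deepTools, featureCounts and DESeq2 were used with builds mm10 and dm6. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here, so values of genes with near-identical copies, of overlapping genes and of antisense genes are uncertain. A read assigned to the wrong copy would move counts between members of a family such as histones. Fly counts were not analysed here, since 0 of the genes in the table are fly genes. Of the columns, 64 matched a sample by name, and 4 that match no sample were not used. Symbols and coordinates came from GENCODE M21 on mm10, which named 55154 of the genes, and 0 entries named no gene. Counts measure shares of a library, so a fall of all mRNAs together leaves them unmoved.

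Groups, comparisons, main tests, gene lists and the rule for named genes were fixed before the data were examined. The main test was edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, glmQLFit and glmQLFTest, two-sided) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment over the genes of a comparison at a threshold of 0.05. The 12 h fit held 52 libraries with 1 coefficient for each of 26 groups (17928 genes, 26 residual degrees of freedom, 99.83% of counts kept, biological coefficient of variation 8.29% at the median, scaling factors 0.539 to 1.174). The fit of the 0 h and 1 h libraries held 12 (15658 genes, 6 residual degrees of freedom, 99.79% of counts, 7.46%, 0.963 to 1.027). Contrasts were IAA against untreated in each of the 13 lines, 1 h against 0 h in RPB1, RPB3 and RPB6, the difference of responses in 4 pairs of lines, each response minus that of wild type, and untreated lines against untreated wild type. CPM values are scaled by the TMM factors unless said to be of all counts. A group without a count was given a floor of 3 counts over the group, and intervals and floors cover counting error only.

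Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry beside it, adjusted over 400 tests (25 lists in 16 treatment comparisons). Of these 125 were called, 48 with the estimated correlation and 229 with fry, which asks only whether a list moves on balance. The lists were Pol II subunits, Pol I and Pol III specific subunits, Pol II elongation and P-TEFb factors, mRNA decay machinery, splicing factors, pluripotency, primitive endoderm, mesoderm and primitive streak, neuroectoderm and epiblast, trophectoderm, 2-cell-like state, embryonic fibroblast, p53 targets, integrated stress response, heat shock and chaperones, interferon response, aryl hydrocarbon receptor targets, immediate-early and other short-lived mRNAs, cytosolic ribosomal proteins, ribosome biogenesis, nuclear-encoded oxidative phosphorylation, mitochondrial-genome mRNAs, replication-dependent histones, DNA replication and mitosis. Lists were also tested between pairs of lines in the same way, adjusted over those tests, a step added after seeing the data. A list needed 3 tested members.

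Genes were named by rule. In each treatment comparison, called genes with a mean of 5 CPM or more over the 4 libraries and no overlap between the groups were ranked, and the 5 highest and 5 lowest log2 fold changes were taken, model-name symbols left out, with fewer named where a comparison repeats the genes of another. The rule added the gene of the degraded subunit, up to 4 members with the smallest adjusted p of each called list and up to 2 of any other, every called aryl hydrocarbon receptor target in wild type, and the 3 highest and 3 lowest genes of each pair of lines. Not every gene that the rule allows is printed. Correlations were computed with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, the exact permutation test with scipy 1.17.1 and figures with matplotlib 3.10.9.

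Depth was 3399838 to 7164928 counts per library in the 12 h set and 8598431 to 13281252 in the other. Steps were tested on simulated counts with 200 changed genes: for RPB4 at 12 h the test recovered 32.8% of genes changed 1.5-fold, 55.2% at 2-fold and 63.6% at 4-fold and called 0.028% of unchanged genes, over 17928 genes. For RPB3 at 1 h it recovered 47.8%, 62.7% and 90.9% and called 0.071%, over 15658 genes. The 2 libraries of a group were compared by chi-square per degree of freedom over genes, which ran from 1.11 (RPB11 after IAA) to 14.7 (untreated RPB7), and no pair held identical values, so each was counted as 1 sample. Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, an absolute log2 fold change of 1 or more, the libraries of a comparison alone, a replicate block, all 64 libraries in one fit for 1 h, and each library left out in turn. Scaling to total counts and to mitochondrial mRNAs, the latter also without either IAA library of RPB3, and leaving out libraries for correlations and for shared against specific subunits, were added after seeing the data.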

Results

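Mouse V6.5 embryonic stem cells were engineered so that 1 subunit of RNA polymerase II (Pol II, the enzyme that transcribes mRNA) carried an auxin-inducible degron, a tag that marks the protein for destruction when the auxin indole-3-acetic acid (IAA) is added. There were 12 such lines, RPB1 to RPB12, and wild-type (WT) cells without a tag. RNA sequencing gave 64 libraries. WT and the 12 degron lines were sequenced untreated and after 12 h of 500 µM IAA (52 libraries in 26 groups of 2), and RPB1, RPB3 and RPB6 at 0 h and 1 h of IAA (12 libraries in 6 groups of 2). Total counts per library ran from 3399838 to 7164928 in the 12 h set (median 5244543). They ran from 8598431 to 13281252 in the 0 h and 1 h set (median 9434286). The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels below are CPM, the counts of a gene scaled to a common library size with TMM, given as mean ± SD of 2 libraries per group, and changes are log2 fold changes ± SE. A gene was called, that is said to have risen or fallen, where the edgeR quasi-likelihood test passed a Benjamini-Hochberg adjusted p of 0.05.

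Loss of a subunit asks how far the mRNA pool of the cell depends on it, and WT in IAA gives the background of the treatment. Of 17928 genes tested at 12 h, 11894 changed in RPB1, 11100 in RPB2, 11065 in RPB8, 10875 in RPB6 and 10595 in RPB5. The count was 8558 in RPB3, 7406 in RPB7, 7059 in RPB10, 6243 in RPB9 and 4240 in RPB11. It was lowest in RPB12 (858), RPB4 (373) and WT (295). The sizes of these counts were not tested against each other.

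**Figure D1:**
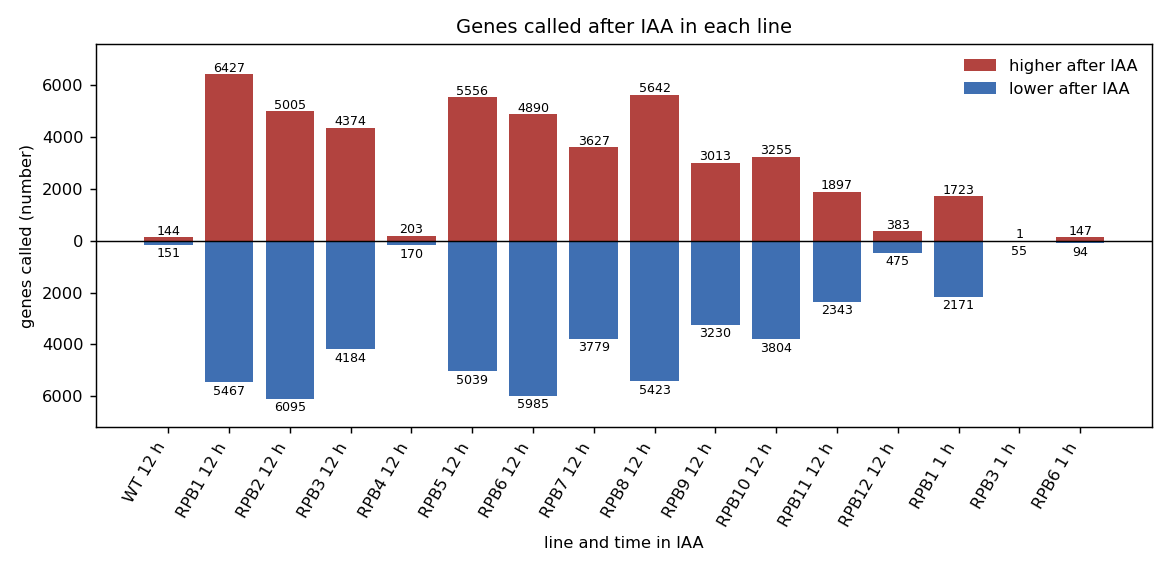
Genes higher (upper bars) and lower (lower bars) after IAA in each line, by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 2 libraries per group. The 12 h counts run from 295 genes in WT to 11894 in RPB1, and the 1 h counts from 56 in RPB3 to 3894 in RPB1.

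TMM scaling takes most genes as unchanged, and 2 other scalings, to the total counts of a library and to its mitochondrial mRNAs, were added after seeing the data. The share of called genes that were higher was, with TMM, total counts and mitochondrial mRNAs in turn, 54.0%, 64% and 33.6% in RPB1, 45.1%, 21.2% and 0.6% in RPB2 and 51.1%, 67.4% and 93.5% in RPB3. It was 52.4%, 57.8% and 25.9% in RPB5, 45%, 23.6% and 0.2% in RPB6 and 49.0%, 58.0% and 13.5% in RPB7. It was 51.0%, 44.1% and 7.9% in RPB8, 48.3%, 59.6% and 32.2% in RPB9, 46.1%, 56.6% and 20.6% in RPB10, 44.7%, 62.1% and 57.3% in RPB11 and 48.8%, 57.1% and 71.4% in WT. In the same order the median log2 fold change of all genes was -0.19, -1.03 and -2.31 in RPB2, -0.13, -0.75 and -2.08 in RPB6 and 0.04, -0.11 and -1.43 in RPB8. It was 0.09, 0.29 and -0.48 in RPB1, 0.06, 0.24 and 0.67 in RPB3 and 0.08, 0.16 and -0.46 in RPB5. With mitochondrial mRNAs it also moved by over 0.1 in RPB7 (-0.38), RPB10 (-0.24), RPB9 (-0.14), RPB4 (0.12), RPB11 (0.11) and in RPB6 at 1 h (0.12), where with total counts it ran from -0.01 to 0.09. In WT it was -0.10 with mitochondrial mRNAs. The values of RPB3 with mitochondrial mRNAs rest on 1 library: these mRNAs took 0.534% of the counts of IAA replicate 1 and 1.72% of those of IAA replicate 2, against 1.27% and 1.30% untreated. Without IAA replicate 1, a fit added after seeing the data, the share was 31.6% and the median -0.18. With RLE size factors the median of all genes was 0.24 in RPB1, 0.14 in RPB8 and 0.00 in RPB2. Changes given here are relative to the TMM scale. Of the 231 called changes of named genes, 0 changed sign with RLE size factors, 0 with total counts and 11 with mitochondrial mRNAs. These were Polr2b, Atp5b and Rplp0 in RPB2, Polr2f, Atp5b, Rplp0, Hspd1, Lin28a and mt-Co1 in RPB6, Polr2g in RPB7 and Polr2h in RPB8. Since mt-Co1 is part of that scaling, its value there (-0.08) lies near 0 by construction. These counts give no absolute amounts per cell, since the fly spike-in was not analysed here.

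The gene of the degraded subunit was examined first. Its mRNA rose at 12 h in 8 lines: Polr2a in RPB1 from 399 ± 5.73 to 2287 ± 16.7 CPM (2.52 ± 0.12), Polr2f in RPB6 (1.63 ± 0.17), Polr2b in RPB2 (1.5 ± 0.092) and Polr2h in RPB8 (0.92 ± 0.13). Smaller rises were found for Polr2l in RPB10 (0.84 ± 0.21), Polr2e in RPB5 (0.56 ± 0.1), Polr2g in RPB7 (0.38 ± 0.12) and Polr2c in RPB3 (0.28 ± 0.086). Scaled to mitochondrial mRNAs, the value turned negative for Polr2f (-0.33), Polr2b (-0.72), Polr2h (-0.59) and Polr2g (-0.03). Polr2e in RPB5 was at 0.01. Polr2g was at 0.13 and not called without untreated replicate 1 of RPB7, and Polr2c at 0.19 without IAA replicate 2 or 0.23 without untreated replicate 1 of RPB3. In the other 4 lines the test was not passed, with 0.17 ± 0.12 for Polr2d in RPB4, -0.39 ± 0.2 for Polr2i in RPB9, 0.34 ± 0.21 for Polr2j in RPB11 and -0.14 ± 0.22 for Polr2k in RPB12. Nor was it passed at 1 h for Polr2a (0.02 ± 0.078), Polr2c (-0.07 ± 0.079) or Polr2f (0.15 ± 0.13). IAA removes the protein, not its mRNA, so these values check neither labels nor depletion. Polr2d and Polr2l each rose in 10 lines and fell in 0, so rises were not limited to the degraded subunit.

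In WT cells 12 h of IAA raised 144 genes and lowered 151. Cdx1, a homeobox gene of the primitive streak and hindgut, rose from 25 ± 4.95 to 67.3 ± 2.13 CPM (1.43 ± 0.18), and Cidea (1.71 ± 0.29), Lhfpl2 (1.53 ± 0.24), Tlx2 (1.45 ± 0.27) and Rasgrp1 (1.44 ± 0.23) rose with it. Utf1, a chromatin factor of undifferentiated stem cells, fell from 73.0 ± 1.93 to 29.3 ± 3.12 CPM (-1.32 ± 0.17), and Id3, an inhibitor of helix-loop-helix factors, fell from 8.06 ± 0.607 to 2.94 ± 0.075 CPM (-1.45 ± 0.31). Mapk4 (-1.43 ± 0.26), Rfesd (-1.17 ± 0.29) and the ERK phosphatase gene Dusp6 (-1.26 ± 0.27) also fell. The only called member of the aryl hydrocarbon receptor list was Cyp1a1, which encodes a xenobiotic-metabolising enzyme and went from 0.39 ± 0.27 to 2.48 ± 0.38 CPM of all counts (2.58 ± 0.6). Among 25 pluripotency genes 8 fell, 1 rose and 16 did not pass (11 and 1 adjusted over the list alone), with Tdh (-0.52 ± 0.08), Zfp42 (-0.49 ± 0.078) and Tdgf1 (-0.40 ± 0.068) beside Utf1 among those that fell (camera, median -0.16, adjusted p = 8.26e-06, and adjusted p = 0.000936 with an estimated correlation). Of 15 mesoderm and primitive streak genes 3 rose, 1 fell and 11 did not pass (5 and 2 adjusted over the list alone) (camera, median 0.49, adjusted p = 0.0107, and adjusted p = 0.0327 with an estimated correlation). Axin2 was higher (0.71 ± 0.13) and Lefty2 lower (-1.10 ± 0.12). Of 28 DNA replication genes 3 fell, 0 rose and 25 did not pass (4 and 0 adjusted over the list alone) (camera, median -0.10, adjusted p = 0.00377, and adjusted p = 0.0292 with an estimated correlation). The 3 were Rrm2, Pola1 and Pcna. Both groups had 2 libraries, and leaving out untreated replicate 1 or 2 or IAA replicate 1 or 2 gave 112, 98, 103 and 92 genes. Such a fit did not call Rfesd in any of the 4 cases (-1.26 to -1.04), Id3 without either IAA library or without untreated replicate 1 (-1.46, -1.41 and -1.36), Dusp6 without IAA replicate 1 (-0.98) or untreated replicate 1 (-1.12), Axin2 without untreated replicate 1 (0.64) and Tlx2 without untreated replicate 2 (1.29).

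RPB4, a subunit of the Pol II stalk, and RPB12 had the fewest genes called among the degron lines in the fit of all 12 h libraries. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling (chromosome 18, 38586247 to 38601415 in mm10), fell in RPB4 from 35.5 ± 4.73 to 2.09 ± 0.22 CPM (-4.06 ± 0.23) and in RPB12 from 38.3 ± 0.742 to 4.38 ± 0.288 CPM (-3.12 ± 0.19). The zinc transporter gene Slc39a14 fell in both lines (-2.57 ± 0.2 and -2.56 ± 0.17), as did Enox1 (-2.42 ± 0.19 and -2.41 ± 0.18). In RPB4 Etv4 (-2.07 ± 0.13) and Nt5e (-2.03 ± 0.23) fell, while Col9a2 (1.99 ± 0.26), Aqp3 (1.58 ± 0.11), Cemip (1.58 ± 0.27) and Spic (1.46 ± 0.21) rose. In RPB12 Aire (-2.66 ± 0.34) and Mapk4 (-2.22 ± 0.35) fell, and Cidea (2.14 ± 0.28), Pramel6 (2.07 ± 0.29) and the trophectoderm gene Cdx2 (2.06 ± 0.31) rose. Neuroectoderm and epiblast genes were lower in both lines: 5 fell, 1 rose and 9 did not pass (5 and 2 adjusted over the list alone) of 15 in RPB4 (camera, median -0.30, adjusted p = 0.000671, and adjusted p = 0.00866 with an estimated correlation). In RPB12 7 fell, 0 rose and 8 did not pass (10 and 1 adjusted over the list alone) (camera, median -0.74, adjusted p = 9.69e-10, and adjusted p = 3.39e-05 with an estimated correlation). Zic2 (-0.67 ± 0.13 and -1.05 ± 0.11) and Dnmt3b (-0.58 ± 0.082 and -0.74 ± 0.079) were among them. In RPB12 17 fell, 0 rose and 10 did not pass (19 and 0 adjusted over the list alone) of 27 integrated stress response genes (camera, median -0.54, adjusted p = 1.98e-25, and adjusted p = 0.000196 with an estimated correlation). Among those that fell were the serine synthesis gene Psat1 (-0.65 ± 0.063) and the amino acid transporter gene Slc7a5 (-0.63 ± 0.075). In RPB4 2 fell, 1 rose and 22 did not pass (6 and 1 adjusted over the list alone) of 25 p53 targets (camera, median -0.11 but 0.02 scaled to mitochondrial mRNAs, adjusted p = 0.0319, and adjusted p = 0.0585 with an estimated correlation). Pmaip1 was lower (-0.98 ± 0.19) and Cdkn1a higher (0.48 ± 0.096).

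Part of the RPB4 and RPB12 response was also seen in WT cells, where Zic2 was at -0.875, Cdkn1a at 0.593 and Aqp3 at 0.559. Of the 373 genes called in RPB4, 87 were called in the same direction in WT and 0 in the opposite one, against 3.1 for independent lists. For RPB12 the numbers were 152 and 1, against 7.1. Each line had its own untreated libraries, so the comparisons share no controls. When the WT change was subtracted, 51 genes passed in RPB4 and 95 in RPB12. The count in RPB4 without untreated replicate 1 or 2 or IAA replicate 1 or 2 was 167, 140, 193 and 156, and Cdkn1a was at 0.43 and not called without untreated replicate 2. In RPB12 the count without untreated replicate 1 or 2 or IAA replicate 1 or 2 was 460, 397, 448 and 406.

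RPB1, the largest subunit, gave 11894 called genes, but RPB2 and RPB6 gave more than it at an absolute log2 fold change of 1 or more (8280 and 7291 against 6975), after subtraction of the WT change (9948 and 9701 against 8795) and scaled to mitochondrial mRNAs (13841 and 13909 against 10420). A set of genes without a count in untreated RPB1 cells appeared after 12 h: Uts2r, a neuropeptide receptor gene, reached 30.4 ± 1.67 CPM, at least 99.0-fold higher, and Ermap 27.0 ± 1.21 CPM, at least 88.0-fold. Colec11 (at least 63.7-fold), Pcdh17 (at least 56.4-fold) and Inka2 (at least 56.3-fold) did likewise, each bound taken at 3 counts over the untreated group and covering counting error only. Foxd3, a forkhead gene of stem cells, fell from 45.8 ± 0.217 to 3.13 ± 1.13 CPM (-3.86 ± 0.24), and Vldlr (-3.79 ± 0.36) and Enox1 (-3.66 ± 0.3) fell with it. Of 25 p53 targets, 21 rose, 3 fell and 1 did not pass (21 and 3 adjusted over the list alone) (camera, median 1.67, adjusted p = 3.11e-07, and adjusted p = 5.15e-05 with an estimated correlation). Among them were the kinase gene Plk2 from 3.99 ± 0.592 to 247 ± 2.35 CPM, Btg2 (4.47 ± 0.14), Pmaip1 (3.9 ± 0.15) and Trp53inp1 (2.80 ± 0.12). Of 44 immediate-early and other short-lived mRNAs, 29 rose, 7 fell and 8 did not pass (29 and 7 adjusted over the list alone) (camera, median 1.53, adjusted p = 1.62e-05, and adjusted p = 0.0561 with an estimated correlation). Examples were Fos from 1.01 ± 0.836 to 116 ± 3.14 CPM, Egr1 (5.6 ± 0.21) and Gadd45b (3.47 ± 0.12). Of 25 pluripotency genes, 20 fell, 0 rose and 5 did not pass (20 and 1 adjusted over the list alone) (camera, median -1.39, adjusted p = 3.47e-10, and adjusted p = 3.39e-05 with an estimated correlation). Among them were Nanog from 858 ± 10.5 to 110.0 ± 8.24 CPM, Fgf4 (-3.33 ± 0.082) and Zfp42 (-2.83 ± 0.085).

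Of 47 ribosome biogenesis genes in RPB1, 39 fell, 1 rose and 7 did not pass (39 and 1 adjusted over the list alone) (camera, median -0.69, adjusted p = 1.21e-10, and adjusted p = 0.0189 with an estimated correlation). Nop56 was at -1.80 ± 0.081. Of 42 splicing factors, 26 fell, 6 rose and 10 did not pass (26 and 6 adjusted over the list alone) (camera, median -0.43, adjusted p = 1.09e-05, and adjusted p = 0.0201 with an estimated correlation). Sf3b3 was at -2.19 ± 0.068 and Srsf3 at -2.32 ± 0.092. DNA replication (camera, median -0.59, adjusted p = 5.54e-05, and adjusted p = 0.00324 with an estimated correlation) and mRNA decay machinery (camera, median -0.40, adjusted p = 0.00127, and adjusted p = 0.00307 with an estimated correlation) were also lower, with Pola1 (-2.18 ± 0.12) and the deadenylase scaffold gene Cnot1 (-1.68 ± 0.11) as examples, while the decay gene Tob1 rose (2.51 ± 0.1). Heat shock genes parted: Hspa1a (5.87 ± 0.2) and Hspa1b (3.76 ± 0.17) rose and the constitutive Hspa8 fell (-2.57 ± 0.075). The list was called lower by camera, its median was -0.33 and its mean 0.01, and the call was lost (adjusted p = 0.379 with an estimated correlation). Genes that were silent in untreated cells of every line gained counts in RPB1: 4373 autosomal protein-coding genes below 0.01 CPM summed to 6.3 ± 0.65 CPM of all counts in untreated RPB1 and 756 ± 8.07 CPM after IAA, against 5.13 ± 0.47 and 18.4 ± 2.37 CPM in WT. The genes were chosen on the untreated libraries, so their low sums there come in part from selection. In the 0 h libraries, of unknown library type and not used in that choice, they summed to 19.4 ± 2.0 CPM in RPB1, 16.9 ± 1.53 in RPB3 and 46.3 ± 1.53 in RPB6. These sums set no baseline for WT. Gm26917, a transcript that overlaps a ribosomal RNA copy and was chosen after its values were seen, was at 176 and 232 CPM of all counts in the untreated libraries of RPB1 and 584 and 897 after IAA.

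**Figure D2:**
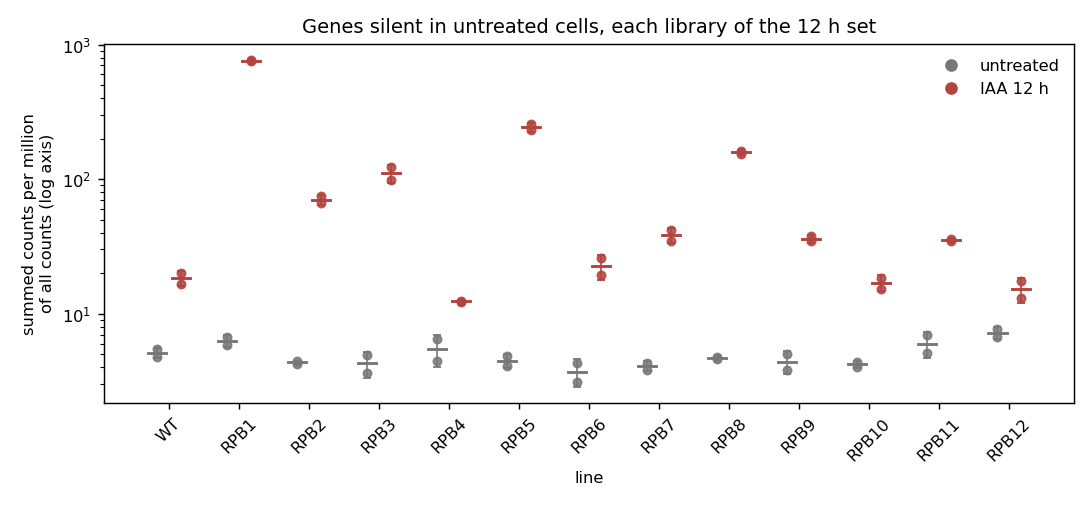
Summed counts of 4373 autosomal protein-coding genes below 0.01 CPM over all untreated libraries, in CPM of all counts on a log axis, for each library of each group. RPB1 after 12 h of IAA lies highest, at a mean of 755.74 CPM, and WT after IAA at 18.4 CPM.

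RPB5 and RPB8 are shared by Pol II with Pol I and Pol III. In RPB5 the proneural gene Neurog2 went from no count to 23.9 ± 0.739 CPM (at least 88.1-fold higher), and the long noncoding RNA Fendrr (at least 56.2-fold), Ltb4r1 (at least 50.1-fold), Espnl (at least 46.6-fold) and Zc3h12d (at least 41.2-fold) followed. In RPB8 Uts2r (at least 127-fold) and Dlx2 (at least 43.2-fold) rose from no count, and Adm, which encodes adrenomedullin, went from 0.09 ± 0.128 to 38.8 ± 0.121 CPM with 1 count in the untreated group. Chac1, a glutathione-degrading enzyme gene, fell in RPB5 from 46.5 ± 10.4 to 1.16 ± 0.781 CPM and in RPB8 from 36.4 ± 4.57 to 0.429 ± 0.607 CPM, and Foxd3 (-4.70 ± 0.31), Vldlr (-4.38 ± 0.36) and Scaper (-4.29 ± 0.31) fell in RPB5. Nlrp12 fell in RPB8 (-4.70 ± 0.28). Of 25 p53 targets 19 rose, 0 fell and 6 did not pass (19 and 0 adjusted over the list alone) in RPB5 (camera, median 1.52, adjusted p = 3.42e-09, and adjusted p = 3.21e-05 with an estimated correlation). In RPB8 18 rose, 1 fell and 6 did not pass (19 and 1 adjusted over the list alone) (camera, median 1.21 but -0.30 scaled to mitochondrial mRNAs, adjusted p = 1.91e-07, and adjusted p = 4.88e-05 with an estimated correlation). Plk2 was at 5.44 ± 0.16 and 6.63 ± 0.15. Of 44 short-lived mRNAs 28 rose, 9 fell and 7 did not pass (29 and 10 adjusted over the list alone) in RPB5 (camera, median 0.60, adjusted p = 0.000269, and adjusted p = 0.104 with an estimated correlation). In RPB8 34 rose, 5 fell and 5 did not pass (34 and 5 adjusted over the list alone) (camera, median 1.72, adjusted p = 9.99e-10, and adjusted p = 0.00697 with an estimated correlation). Examples were Junb (3.36 ± 0.14) in RPB5 and Fos (7.44 ± 0.23) and Gadd45b (4.68 ± 0.12) in RPB8. The 2-cell-like genes Zscan4d in RPB5 (1.70 ± 0.27) and Zscan4a in RPB8 (2.52 ± 0.46) rose with their list, 9 rose, 0 fell and 3 did not pass (10 and 0 adjusted over the list alone) of 12 in RPB5 (camera, median 1.90 or 1.77 with members absent from 1 group at their bound, adjusted p = 0.0241, and adjusted p = 0.0858 with an estimated correlation). In RPB8 11 rose, 0 fell and 1 did not pass (11 and 0 adjusted over the list alone) (camera, median 2.26, adjusted p = 0.0118, and adjusted p = 0.0583 with an estimated correlation). Zscan4 and Usp17l genes have near-identical copies, so their counts are uncertain. In RPB8 Gm26917 was at 320 and 152 CPM of all counts untreated and 1675 and 1868 after IAA.

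In RPB3, which pairs with RPB11 in the enzyme, Plk2 rose from 4.28 ± 1.94 to 69.3 ± 0.045 CPM, Col11a2 (4.46 ± 0.38) and Vwa5b2 (3.9 ± 0.4) rose, and Dnhd1 went from 0.177 ± 0.25 to 19.6 ± 2.06 CPM with 2 counts in the untreated group. Ubap1l (-5.77 ± 0.39), Enox1 (-5.55 ± 0.39), Chac1 (-5.16 ± 0.25), Spry4 (-4.79 ± 0.3) and Vldlr (-4.71 ± 0.35) fell. Of 27 integrated stress response genes 24 fell, 1 rose and 2 did not pass (26 and 1 adjusted over the list alone) (camera, median -1.31, adjusted p = 1.87e-18, and adjusted p = 0.00154 with an estimated correlation). Examples were the mitochondrial folate enzyme gene Mthfd2 from 343 ± 0.361 to 69.7 ± 0.956 CPM, Psat1 (-1.83 ± 0.064) and Aldh18a1 (-1.76 ± 0.082). Of 25 p53 targets 17 rose, 4 fell and 4 did not pass (18 and 4 adjusted over the list alone) (camera, median 0.87, adjusted p = 1.91e-07, and adjusted p = 4.88e-05 with an estimated correlation). Examples were Btg2 (3.11 ± 0.13) and the cell cycle inhibitor gene Cdkn1a (1.58 ± 0.093). Cytosolic ribosomal protein genes were lower, 68 fell, 0 rose and 13 did not pass (73 and 0 adjusted over the list alone) of 81 (camera, median -0.43 but 0.41 scaled to mitochondrial mRNAs, adjusted p = 2.52e-12, and adjusted p = 0.403 with an estimated correlation). The 2 IAA libraries of RPB3 stood apart from each other, with a chi-square per degree of freedom of 7.27 and mitochondrial mRNA at 0.534% and 1.72% of counts. Without IAA replicate 1 the median of ribosomal protein genes scaled to mitochondrial mRNAs was -0.70. Gm26917 was at 271 and 218 CPM of all counts untreated and 940 and 635 after IAA.

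RPB9, a peripheral subunit, and RPB11 shared several named genes. Utf1 (chromosome 7, 139943789 to 139945112 in mm10) fell in RPB9 from 142 ± 14.5 to 18.2 ± 0.874 CPM and in RPB11 from 115 ± 29.0 to 11.5 ± 0.01 CPM, and Ubap1l fell in both (-3.68 ± 0.26 and -2.48 ± 0.22). In RPB9 Chac1 (-4.55 ± 0.23) and the small nucleolar RNA host gene Snhg5 (-2.93 ± 0.16) fell and Ovgp1 (3.55 ± 0.35), Slc16a8 (3.44 ± 0.38) and Prob1 (3.09 ± 0.3) rose, while the activin subunit gene Inhbb went from 14.5 ± 0.105 to 0.242 ± 0.112 CPM with 3 counts after IAA. In RPB11 the cadherin gene Cdh3 (-2.97 ± 0.16), the RNA sensor gene Ddx58 (-2.55 ± 0.19) and Kifc3 (-2.47 ± 0.18) fell and Oas1d (3.02 ± 0.36), Tarm1 (2.48 ± 0.28) and Arsg (2.28 ± 0.38) rose. Of 27 integrated stress response genes 23 fell, 0 rose and 4 did not pass (24 and 0 adjusted over the list alone) in RPB9 (camera, median -0.78, adjusted p = 3.02e-17, and adjusted p = 0.00204 with an estimated correlation). In RPB11 21 fell, 0 rose and 6 did not pass (22 and 0 adjusted over the list alone) (camera, median -0.68, adjusted p = 6.17e-18, and adjusted p = 0.00177 with an estimated correlation). The list's transcription factor gene Atf4 fell in RPB9 (-1.72 ± 0.11) and the seryl-tRNA synthetase gene Sars in RPB11 (-1.07 ± 0.089). Primitive endoderm genes were lower in RPB11, 5 fell, 1 rose and 7 did not pass (5 and 1 adjusted over the list alone) of 13 (camera, median -0.51, adjusted p = 0.025, and adjusted p = 0.063 with an estimated correlation). The laminin gene Lama1 was at -1.43 ± 0.12. Gm26917 was at 217 and 256 CPM of all counts in untreated RPB9 and 676 and 722 after IAA. The RPB11 count was 2751 without its IAA replicate 1 and 2711 without its IAA replicate 2.

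In RPB7, the partner of RPB4 in the stalk, Chac1 fell from 132 ± 3.16 to 7.46 ± 1.12 CPM, and Enox1 (-4.50 ± 0.32) and Mettl25 (-4.06 ± 0.36) fell, while the interleukin gene Il17f rose from 1.55 ± 0.464 to 38.3 ± 2.63 CPM with Rnf223 (4.52 ± 0.31), Nup210l (4.01 ± 0.36) and Isoc2b (3.92 ± 0.3). Of 27 integrated stress response genes 26 fell, 0 rose and 1 did not pass (27 and 0 adjusted over the list alone) (camera, median -1.08, adjusted p = 1.7e-20, and adjusted p = 0.000863 with an estimated correlation), Atf4 (-1.71 ± 0.11) and Cth (-1.72 ± 0.096) among them. Splicing factors were lower too, 25 fell, 4 rose and 13 did not pass (25 and 5 adjusted over the list alone) of 42 (camera, median -0.34, adjusted p = 3.75e-06, and adjusted p = 0.0143 with an estimated correlation). Srsf3 was at -2.79 ± 0.093. In RPB10, another shared subunit, Zfp750 (5.41 ± 0.4), Zfp612 (4.26 ± 0.45) and Ovgp1 (4.16 ± 0.29) rose, and the guidance factor gene Ntn1 (-3.96 ± 0.26), Mipol1 (-4.20 ± 0.3), Dip2c (-3.61 ± 0.27) and Sfmbt2 (-3.59 ± 0.25) fell. Of 25 p53 targets 22 rose, 1 fell and 2 did not pass (22 and 1 adjusted over the list alone) in RPB10 (camera, median 1.23, adjusted p = 1.33e-18, and adjusted p = 4.5e-08 with an estimated correlation). Examples were Plk2 from 3.79 ± 0.13 to 114 ± 2.37 CPM and Ccng1 (2.33 ± 0.1). The 2 untreated libraries of RPB7 stood furthest apart of all groups, with a chi-square per degree of freedom of 14.7, and Gm26917 was at 204 and 151 CPM of all counts in them and 1294 and 1349 after IAA.

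RPB2, the second largest subunit, and the shared subunit RPB6 gave a pool that was richer in mRNAs of mitochondria and ribosomes. The mitochondrial mRNA mt-Co1 rose in RPB2 from 3629 ± 88.8 to 19259 ± 66 CPM and in RPB6 from 3317 ± 79.0 to 12234 ± 70.2 CPM. Transcripts that overlap a ribosomal RNA copy, chosen after their values were seen, took other shares of the same libraries: in CPM of all counts Gm26917 was at 222 and 151 in the untreated libraries of RPB2 and at 13042 and 13523 after IAA, and Gm42418 at 43.1 and 44.0 and then 1833 and 1866. In RPB6 Gm26917 was at 200 and 278 and then 518 and 453 CPM, and in WT at 274 and 169 and then 181 and 118. Of 81 cytosolic ribosomal protein genes 79 rose, 1 fell and 1 did not pass (79 and 1 adjusted over the list alone) in RPB2 (camera, median 1.74 but -0.47 scaled to mitochondrial mRNAs, adjusted p = 3.09e-26, and adjusted p = 0.177 with an estimated correlation). In RPB6 79 rose, 0 fell and 2 did not pass (79 and 0 adjusted over the list alone) (camera, median 1.36 but -0.60 scaled to mitochondrial mRNAs, adjusted p = 9.52e-25, and adjusted p = 0.197 with an estimated correlation). Rplp0 was at 2.11 ± 0.083 and 1.66 ± 0.082. All 78 nuclear-encoded oxidative phosphorylation genes rose in both (78 adjusted over the list alone), with Atp5b at 1.93 ± 0.07 and 1.44 ± 0.07 (camera, adjusted p = 0.124 and 0.132 with an estimated correlation). These directions hold relative to the other mRNAs of the library: scaled to mitochondrial mRNAs, the medians were -0.40 and -0.53 for oxidative phosphorylation, and Rplp0 (-0.11 and -0.31) and Atp5b (-0.28 and -0.52) turned negative. Zfp105 fell in RPB2 from 24.5 ± 0.8 to 0 ± 0 CPM, at least 34.7-fold lower, and Fjx1 (at least 17-fold) and Plekhh3 in RPB6 (at least 24.7-fold) also fell to no count, with bounds at 3 counts over the IAA group. Spry4 went from 74.6 ± 2.74 to 0.471 ± 0.007 CPM in RPB2 with 2 counts after IAA. Of 44 short-lived mRNAs 33 fell, 6 rose and 5 did not pass (34 and 7 adjusted over the list alone) in RPB2 (camera, median -2.14, adjusted p = 2.98e-06, and adjusted p = 0.0344 with an estimated correlation). In RPB6 31 fell, 4 rose and 9 did not pass (32 and 4 adjusted over the list alone) (camera, median -1.22, adjusted p = 7.24e-06, and adjusted p = 0.043 with an estimated correlation). The survival gene Mcl1 (-2.99 ± 0.091 and -2.75 ± 0.085) and Mycn (-3.73 ± 0.16 and -3.10 ± 0.13) were among those that fell.

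The p53 targets also fell in these lines, 15 fell, 2 rose and 8 did not pass (15 and 2 adjusted over the list alone) of 25 in RPB2 (camera, median -0.75, adjusted p = 0.00835, and adjusted p = 0.0225 with an estimated correlation). In RPB6 16 fell, 3 rose and 6 did not pass (17 and 3 adjusted over the list alone) (camera, median -0.84, adjusted p = 0.0108, and adjusted p = 0.026 with an estimated correlation). Sesn2 (-2.74 ± 0.14 and -3.59 ± 0.14) and the p53 ubiquitin ligase gene Mdm2 (-1.75 ± 0.15 and -2.12 ± 0.15) were among them, and Plk2 rose in RPB6 (2.44 ± 0.23). Among pluripotency genes Fgf4 (-4.02 ± 0.11 and -3.97 ± 0.094), Zfp42 (-4.03 ± 0.099 and -2.69 ± 0.087) and Klf4 in RPB2 (-4.31 ± 0.17) fell, and Lin28a was higher in RPB6 (1.90 ± 0.074, but -0.07 scaled to mitochondrial mRNAs). Replication-dependent histone genes, whose copies share reads and whose values are uncertain, rose in both lines, 15 rose, 0 fell and 10 did not pass (15 and 0 adjusted over the list alone) of 25 in RPB2 (camera, median 2.05 but -0.12 scaled to mitochondrial mRNAs, adjusted p = 0.00598, and adjusted p = 0.136 with an estimated correlation). In RPB6 22 rose, 0 fell and 3 did not pass (23 and 0 adjusted over the list alone) (camera, median 2.49, adjusted p = 0.000114, and adjusted p = 0.043 with an estimated correlation). The small nuclear RNA gene Rn7sk, which has many genomic copies and is likewise uncertain, rose in RPB6 from 0.597 ± 0.59 to 161 ± 3.73 CPM. Heat shock genes split in RPB6, with Hspd1 higher (1.30 ± 0.069, but -0.66 scaled to mitochondrial mRNAs) and Dnajb1 lower (-2.60 ± 0.12) (camera, median 0.99 but -0.98 scaled to mitochondrial mRNAs, adjusted p = 0.0242, and adjusted p = 0.352 with an estimated correlation).

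The 25 lists were then read across the 13 comparisons at 12 h. Pluripotency was lower in 12, all but RPB4, and each call held with an estimated correlation. p53 targets were higher in RPB1, RPB3, RPB5, RPB8, RPB9, RPB10 and RPB11 and lower in RPB2, RPB4 and RPB6, and held in all but RPB4. In RPB9 and RPB11 their medians were 0.15 and 0.04, with 10 members higher and 3 lower in each. Integrated stress response genes were lower in RPB1, RPB3, RPB5, RPB7, RPB8, RPB9, RPB11 and RPB12, and the calls in RPB1, RPB5 and RPB8 were lost (adjusted p = 0.0879 to 0.365 with an estimated correlation). Ribosome biogenesis was lower in 8 comparisons and held only in RPB1 (0.0756 to 0.374 in the others, with Nop56 an example in RPB1), and mitosis was lower in 7 with 0 held (0.08 to 0.358). Splicing factors were lower in 6 and higher in RPB6, with 4 held and 3 lost (0.08 to 0.116). DNA replication was lower in 5 and held in 4 (0.08 in RPB11). Cytosolic ribosomal proteins were higher in RPB2, RPB6 and RPB8 and lower in WT, RPB3 and RPB11. Oxidative phosphorylation was higher in RPB2, RPB5, RPB6 and RPB8 and lower in WT and RPB3. Mitochondrial-genome mRNAs were higher in RPB2, RPB6 and RPB8. The calls of these 3 lists were all lost (0.124 to 0.803). Short-lived mRNAs were higher in RPB1, RPB5, RPB8, RPB10 and RPB11 and lower in RPB2 and RPB6, with those in RPB8, RPB2 and RPB6 held and 4 lost (0.0561 to 0.104). Aryl hydrocarbon receptor targets were higher in 6, held in RPB4, RPB11 and RPB12 and lost in RPB3, RPB9 and RPB10 (0.0889 to 0.225). In those 3 lines their medians were 1.56, 1.15 and 1.2, or 0.37, 0.62 and 0.93 with members absent from 1 group at their bound.

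Of the smaller groups, Pol II subunit genes were higher in RPB2, RPB6 and RPB8 with 0 held (0.128 to 0.365), and 11 of 12 rose in RPB6. Pol I and Pol III subunit genes were lower in RPB1, RPB3 and RPB5, held in RPB1 (0.116 and 0.124 in the others). The 2-cell-like list was higher in RPB5, RPB6 and RPB8 with 0 held (0.0583 to 0.12), and in RPB6 its median was 1.40, or 1.33 with members absent from 1 group at their bound. Replication-dependent histones were higher in RPB2, RPB5, RPB6 and RPB8 and lower in WT, held in RPB6 (0.131 to 0.172 in the others). Heat shock genes were called in RPB1 and RPB6 and lost in both (0.352 to 0.379). Single calls that held were mRNA decay machinery in RPB1 and mesoderm in WT. Those that were lost were primitive endoderm in RPB11 (0.063), trophectoderm in RPB12 (0.0889) and interferon response in RPB4 (0.0817). Cdx2 was 1 of 2 trophectoderm members that rose, and the interferon median was -0.16, or -0.13 at the bounds. Neuroectoderm was lower in RPB4 and RPB12 and held in both. Pol II elongation and P-TEFb factors (smallest camera adjusted p = 0.22, 19 lower and 12 higher in RPB8) and embryonic fibroblast genes (0.12) were not called at 12 h. Of the 125 called list tests at both times, 0 medians changed sign with RLE size factors, 4 with total counts and 27 with mitochondrial mRNAs. With total counts these were pluripotency in RPB11 (0.01), Pol I and Pol III subunits in RPB3 (0.05), Pol II subunits in RPB2 (-0.01) and splicing factors in RPB6 (-0.24). With mitochondrial mRNAs 8 lists of RPB3 turned positive: pluripotency (0.26), splicing factors (0.38), DNA replication (0.50), mitosis (0.42), ribosome biogenesis (0.46), oxidative phosphorylation (0.52), cytosolic ribosomal proteins (0.41) and Pol I and Pol III subunits (0.61). Without IAA replicate 1 of RPB3, with its low mitochondrial mRNA, 0 of these 8 changed sign. Pol II subunits turned negative in RPB2 (-1.36), RPB6 (-1.14) and RPB8 (-0.85). So did oxidative phosphorylation in RPB5 (-0.15) and RPB8 (-0.59), cytosolic ribosomal proteins in RPB8 (-0.68), and splicing factors (-1.58) and the 2-cell-like list (-0.54) in RPB6. DNA replication in RPB11 (0.01) and ribosome biogenesis in RPB4 (0.02) moved past 0.

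**Figure D3:**
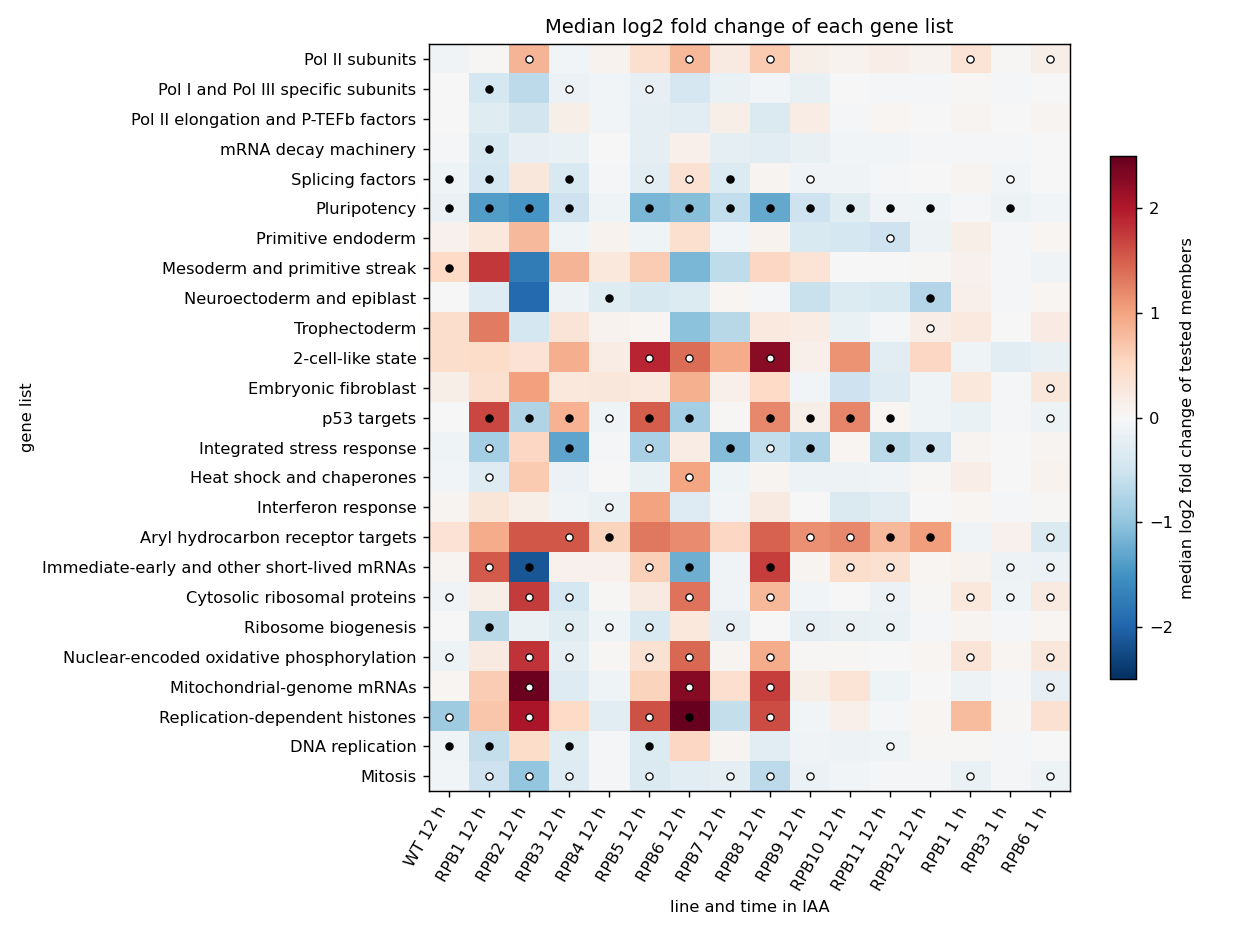
Median log2 fold change of each of 25 gene lists (vertical axis) in each line and time in IAA (horizontal axis), as colour. White dots mark lists called by camera at an adjusted p under 0.05 and black dots those also called with an estimated correlation, 125 and 48 of 400 tests. Scaled to mitochondrial mRNAs, 27 of the 125 medians change sign.

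Some genes moved in every degron line at 12 h. The 17 that fell in all 12 lines included Spry4 (median log2 fold change -3.11 over lines, range -7.24 to -1.16), Utf1 (-2.04, -3.33 to -0.87), the imprint regulator Zfp57 (-1.33, -2.92 to -0.32), the Polycomb partner Jarid2 (-0.53, -1.96 to -0.22) and Kifc3 (-1.89, -2.76 to -0.65). Utf1, Spry4 and Zfp57 fell in WT as well. Without IAA replicate 2 of WT Spry4 was at -1.69 and not called. The 3 that rose in all 12 were Cyp1a1, the creatine transporter gene Slc6a8 (0.61, 0.29 to 1.32) and Lrpap1 (0.64, 0.25 to 1.44). Independent lists of these lengths gave 0.0 genes of either kind. These genes fall outside the rule for named genes and were chosen after their values were seen. Spry4 and other genes near 0 counts after IAA in RPB2 have fitted values that are no bound.

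Cyp1a1 (chromosome 9, 57687928 to 57703824 in mm10), a target of the aryl hydrocarbon receptor, was given in CPM of all counts. It went from 0.25 ± 0.09 to 34.8 ± 3.98 CPM in RPB10, from 0.48 ± 0.22 to 26.7 ± 0.35 in RPB5, from 0.49 ± 0.2 to 25 ± 1.29 in RPB11 and from 0.53 ± 0.46 to 20.8 ± 2.02 in RPB12. It reached 20.1 ± 3.46 CPM in RPB8, 19.1 ± 1.83 in RPB1, 16.9 ± 2.14 in RPB3, 16.7 ± 1.35 in RPB9 and 16.2 ± 2.06 in RPB4, and 1.61 ± 1.16 in RPB7, 1.22 ± 0.16 in RPB6 and 0.63 ± 0.17 in RPB2. The change differed from that of WT in 6 lines (RPB1, RPB3, RPB4, RPB5, RPB8 and RPB10), by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the genes of each line. Their untreated groups held 1, 2, 0, 5, 0 and 3 counts of Cyp1a1 in turn, and that of WT 4. A fold change fitted on 3 or fewer untreated counts is no measurement, so the size is given for RPB5 only. The difference was 3.12 ± 1.04 in RPB5 (adjusted p = 0.0155). RPB4, with no untreated count, passed at adjusted p = 0.049, and RPB11 (2.98 ± 1.03, adjusted p = 0.0593) and RPB9 (2.82 ± 1.05, adjusted p = 0.0623) did not pass. The related Cyp1b1 reached 2.54 ± 0.161 CPM in RPB3 from no count, and Nqo1 rose in RPB4 (0.55 ± 0.092), RPB9 (0.74 ± 0.087) and RPB11 (1.06 ± 0.089).

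**Figure D4:**
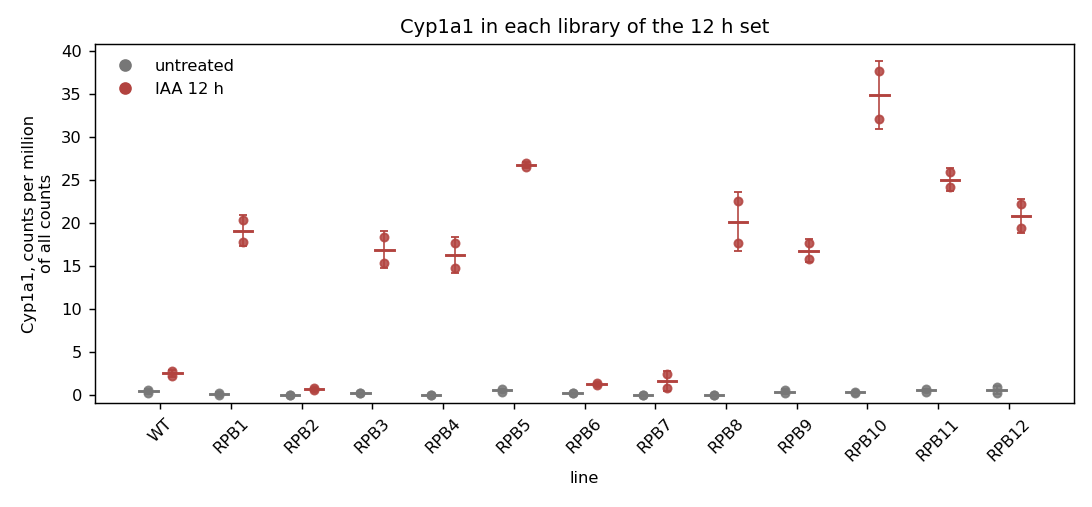
Cyp1a1 in CPM of all counts in each library, untreated and after 12 h of IAA, for WT and the 12 degron lines. The mean after IAA runs from 0.63 CPM in RPB2 to 34.83 CPM in RPB10, and is 2.48 CPM in WT.

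Lines of subunits that lie together in the enzyme were tested for different responses, which clones may also give. The stalk subunits RPB4 and RPB7 differed in 4397 genes: the Nodal antagonist gene Lefty2 went from 87.5 ± 11.8 to 105 ± 2.23 CPM in RPB4 and from 37.0 ± 0.309 to 2.25 ± 0.454 CPM in RPB7 (difference 4.31 ± 0.22), and the interleukin gene Il17f (-4.29 ± 1.0) and Isoc2b (-4.66 ± 1.0) differed the other way. Integrated stress response genes were 1.17 higher in RPB4 at the median (camera, adjusted p = 5.52e-21, and adjusted p = 0.000448 with an estimated correlation), and pluripotency genes 0.42 (adjusted p = 9.62e-07, and 3e-04 with an estimated correlation). Without untreated replicate 2 of RPB4 the differences of Il17f (-4.08) and Isoc2b (-3.05) did not pass. The share of these genes higher in RPB4 was 55.9% with TMM, 50.7% with RLE size factors, 51.3% with DESeq2, 47.1% scaled to total counts and 96.3% scaled to mitochondrial mRNAs. RPB3 and RPB11 differed in 2213 genes, with Col11a2 (3.91 ± 0.74) and the lipid transfer protein gene Mttp (2.76 ± 0.37) higher in RPB3 and Jdp2 (-3.52 ± 0.39) and Chac1 (-3.42 ± 0.35) lower. Median differences were 0.59 for p53 targets (camera, adjusted p = 4.09e-10, and 7.16e-06 with an estimated correlation) and -0.59, but 0.06 scaled to mitochondrial mRNAs (-1.10 without IAA replicate 1 of RPB3), for integrated stress response genes (adjusted p = 1.24e-15, and 0.00187 with an estimated correlation). This count was 1365 without untreated replicate 1 of RPB3 and 1455 without IAA replicate 2 of RPB11, and its share higher in RPB3 was 44.6% with TMM, 54.8% with RLE size factors, 51.3% with DESeq2, 62.3% scaled to total counts and 95.9% scaled to mitochondrial mRNAs, or 9.3% without IAA replicate 1 of RPB3.

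The catalytic subunits RPB1 and RPB2 differed in 11227 genes. Trim12a went from 5.52 ± 0.686 to 2.10 ± 0.59 CPM in RPB1 and from 4.38 ± 1.75 to 31.7 ± 5.20 CPM in RPB2 (difference -4.20 ± 0.44), and Dph6, a diphthamide synthesis gene, from 34.3 ± 2.48 to 5.32 ± 0.676 CPM and from 30.9 ± 1.62 to 63.1 ± 2.91 CPM (-3.71 ± 0.26). Fjx1 rose in RPB1 from 8.50 ± 0.442 to 22.4 ± 1.06 CPM and fell to no count in RPB2. The median difference was 2.98 for p53 targets (camera, adjusted p = 2.81e-07, and 5.82e-05 with an estimated correlation), 3.56 for short-lived mRNAs (adjusted p = 2.03e-13, and 0.000889 with an estimated correlation) and -1.35, but 0.29 scaled to mitochondrial mRNAs, for splicing factors (adjusted p = 4.72e-08, and 0.00228 with an estimated correlation). RPB9 and RPB1 differed in 6836 genes. The Notch ligand gene Dll1 was at 0.162 ± 0.001 CPM after IAA in RPB9 and 37.9 ± 0.408 in RPB1, and Rasgrp1 (3.76 ± 0.47) and Cbr3 (3.40 ± 0.33) were higher in RPB9. Median differences were -1.27 for p53 targets (camera, adjusted p = 1.02e-08, and 1.61e-05 with an estimated correlation) and 0.64 for pluripotency genes (adjusted p = 3.21e-07, and 0.000208 with an estimated correlation). Of the genes that differed between RPB1 and RPB2, 56.0% were higher in RPB1, 81.2% scaled to total counts and 99.2% scaled to mitochondrial mRNAs. Of those that differed between RPB9 and RPB1, 54.4% were higher in RPB9, 44.3% with RLE size factors, 47.6% with DESeq2, 45.4% scaled to total counts and 72.8% scaled to mitochondrial mRNAs.

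Responses were also correlated across all 17928 genes for the 66 pairs of degron lines, which share no controls. Genes are not independent replicates, so no p-value was computed. The median Pearson r was 0.212 and the median Spearman rho 0.195. RPB1 with RPB5 gave the highest r, 0.785, and RPB4 with RPB7 the lowest, 0.000. Neither rank held under each measure: RPB3 with RPB6 and RPB2 with RPB11 had the lowest Spearman rho (-0.026, against 0.013 for RPB4 with RPB7). Over genes at 10 CPM or more RPB3 with RPB6 had the lowest r (-0.126, against 0.063) and RPB2 with RPB6 the highest. Leaving out IAA replicate 2 of RPB4 gave -0.031 for that pair, and the range over its 8 libraries was -0.031 to 0.046. RPB3 with RPB11 had 0.514 (rank 15 of 66). RPB1 with RPB2 had 0.213 (rank 33), 0.137 without IAA replicate 1 of RPB2 and 0.045 over genes at 10 CPM or more. RPB2 with RPB6 had 0.634, and 0.906 over the 9911 genes at a mean of 10 CPM or more. With the WT change subtracted from each line the median r was 0.392. Simulated lines without any effect gave 0.460 because they share the WT libraries, and the covariance was 0.812 against a simulated 0.303 over 5 simulations. The WT libraries cannot be split into parts of 2 libraries, so part of this excess may come from the shared controls.

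**Figure D5:**
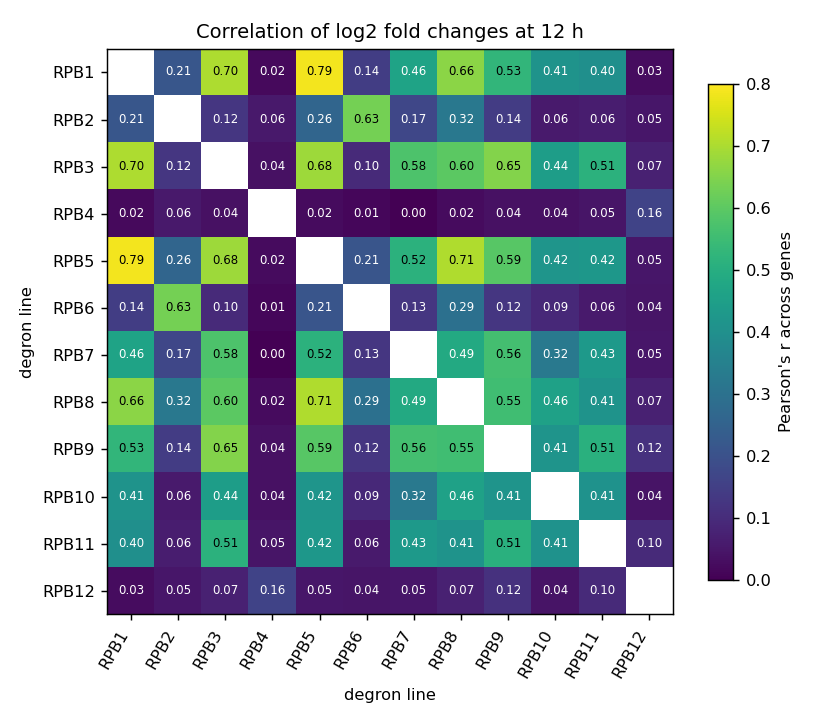
Pearson correlation, across 17928 genes, of log2 fold changes at 12 h for each pair of the 12 degron lines, as colour. The 66 values run from 0.000 to 0.785.

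RPB5, RPB6, RPB8, RPB10 and RPB12 also belong to Pol I and Pol III. For each of 25 gene lists the mean log2 fold change in these 5 lines was set against that in the other 7 by an exact two-sided permutation test over all 792 splits. At an adjusted p of 0.05 this exact permutation test passed 0 lists, 1 was under 0.05 unadjusted, and the smallest adjusted p was 0.505. With the median of members 0 lists passed, 1 was under 0.05 unadjusted, and the smallest adjusted p of that exact permutation test was 0.221. In both it was the 2-cell-like list, and the smallest p that the splits allow is 0.00126.

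At 1 h of IAA RPB1 showed 1723 genes higher and 2171 lower of 15658 tested. The small nucleolar RNA host genes Snhg5 from 98.2 ± 3.34 to 22.8 ± 0.7 CPM and Snhg15 (-2.29 ± 0.2) fell, with the copper chaperone gene Cox17 (-2.12 ± 0.17), and Spry4 fell from 18.4 ± 0.801 to 5.34 ± 0.642 CPM. Mien1 (2.02 ± 0.25), Etfb (1.98 ± 0.31), the prefoldin gene Pfdn6 (1.61 ± 0.25) and the respiratory chain gene Uqcr11 (1.58 ± 0.26) rose. Rps10 (-2.67 ± 0.23) and Atp5k (1.76 ± 0.32) have copies in the genome and are uncertain. Of 81 cytosolic ribosomal protein genes 49 rose, 1 fell and 31 did not pass (58 and 1 adjusted over the list alone) (camera, median 0.27, adjusted p = 1.89e-12, and adjusted p = 0.263 with an estimated correlation). Rps16 was at 0.74 ± 0.079 and Rpl28 at 1.02 ± 0.12. Of 78 oxidative phosphorylation genes 43 rose, 0 fell and 35 did not pass (48 and 1 adjusted over the list alone) (camera, median 0.33, adjusted p = 2.57e-09, and adjusted p = 0.471 with an estimated correlation), and of 12 Pol II subunit genes 5 rose, 0 fell and 7 did not pass (5 and 0 adjusted over the list alone) (camera, median 0.34, adjusted p = 0.000671, and adjusted p = 0.229 with an estimated correlation). Polr2j was at 1.32 ± 0.17. Mitosis genes were lower, 12 fell, 2 rose and 13 did not pass (14 and 2 adjusted over the list alone) of 27 (camera, median -0.17, adjusted p = 0.0319, and adjusted p = 0.329 with an estimated correlation). Hmmr was at -0.47 ± 0.088. Fold changes were related to exonic length across 15646 genes (Spearman rho -0.202), shorter genes lying higher, and Gm26917, which overlaps a ribosomal RNA copy, was at 187 and 195 CPM of all counts at 0 h and 520 and 531 at 1 h. The growth factor gene Fgf4 of the pluripotency list fell (-0.83 ± 0.072), while that list as a whole was not called. The count was 1380 without 0 h replicate 1, 1861 without 1 h replicate 1 and 1618 without 1 h replicate 2.

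RPB3 at 1 h gave 55 genes lower and 1 higher. Spry4 fell from 22.9 ± 1.45 to 8.61 ± 1.56 CPM, and Snhg5 (-1.27 ± 0.094), Snhg15 (-1.33 ± 0.16) and Dancr (-1.17 ± 0.15), host genes or noncoding RNAs, fell with it. Of 25 pluripotency genes 2 fell, 0 rose and 23 did not pass (9 and 0 adjusted over the list alone) (camera, median -0.13, adjusted p = 1.26e-05, and adjusted p = 0.0211 with an estimated correlation). The called ones were Fgf4 (-0.65 ± 0.07) and Tbx3 (-0.42 ± 0.068). Of 43 short-lived mRNAs 4 fell, 0 rose and 39 did not pass (15 and 9 adjusted over the list alone), with Spry2 (-0.75 ± 0.11), Pim3 (-0.52 ± 0.078) and Pim1 (-0.46 ± 0.08) beside Spry4. That list was called lower by camera with a median of -0.12 and a mean of 0.01, and the call was lost (adjusted p = 0.222 with an estimated correlation). Splicing factors, of which 0 fell, 0 rose and 42 did not pass (1 and 0 adjusted over the list alone) (camera, median -0.06 but 0.02 scaled to mitochondrial mRNAs, adjusted p = 0.00292, and adjusted p = 0.374 with an estimated correlation), and cytosolic ribosomal proteins, of which 1 fell, 0 rose and 80 did not pass (1 and 0 adjusted over the list alone) (camera, median -0.10, adjusted p = 3.53e-08, and adjusted p = 0.374 with an estimated correlation), were called lower. The 2 libraries at 1 h differed more than most pairs, with a chi-square per degree of freedom of 9.16 and a difference that followed exonic length at rho 0.323. The number of genes called was 29 without either 0 h replicate and 238 without 1 h replicate 1. Without 0 h replicate 2 the calls of Pim1 (-0.43), Pim3 (-0.47) and Tbx3 (-0.39) ended, and without 0 h replicate 1 that of Pim1 (-0.48).

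RPB6 at 1 h, where fold changes were also related to exonic length (Spearman rho -0.183), gave 147 genes higher and 94 lower. Spry4 fell from 51.4 ± 0.874 to 19.9 ± 0.767 CPM, Nlrp12 (-1.08 ± 0.18), the hyaluronan synthase gene Has3 (-0.81 ± 0.2) and Plppr3 (-0.80 ± 0.19) fell, and Etfb (1.74 ± 0.28), Polr2l (1.29 ± 0.25) and Pfdn6 (1.2 ± 0.25) rose. Of 81 cytosolic ribosomal protein genes 22 rose, 1 fell and 58 did not pass (50 and 2 adjusted over the list alone) (camera, median 0.23, adjusted p = 3.62e-15, and adjusted p = 0.219 with an estimated correlation), and of 78 oxidative phosphorylation genes 10 rose, 0 fell and 68 did not pass (39 and 0 adjusted over the list alone) (camera, median 0.28, adjusted p = 9.77e-14, and adjusted p = 0.365 with an estimated correlation). Of 43 short-lived mRNAs 5 fell, 0 rose and 38 did not pass (8 and 1 adjusted over the list alone) (camera, median -0.14, adjusted p = 0.000418, and adjusted p = 0.0817 with an estimated correlation). Examples were Egr1 (-1.67 ± 0.33), Dusp6 (-0.55 ± 0.091) and Spry2 (-0.53 ± 0.095). In the aryl hydrocarbon receptor list 2 fell, 0 rose and 5 did not pass (2 and 0 adjusted over the list alone) of 7 (camera, median -0.36, adjusted p = 0.00736, and adjusted p = 0.116 with an estimated correlation), Tiparp (-0.63 ± 0.098) and Nfe2l2 (-0.36 ± 0.087). Also called, with 0 members past the threshold, were the embryonic fibroblast list (camera, median 0.29, adjusted p = 0.0347, and adjusted p = 0.34 with an estimated correlation), p53 targets (camera, median -0.12, adjusted p = 0.0371, and adjusted p = 0.387 with an estimated correlation), mitochondrial-genome mRNAs (camera, median -0.21, adjusted p = 0.0171, and adjusted p = 0.143 with an estimated correlation) and mitosis (camera, median -0.13, adjusted p = 0.00356, and adjusted p = 0.199 with an estimated correlation). The number of genes called was 17 without 0 h replicate 1, 3 without 0 h replicate 2, 2 without 1 h replicate 1 and 425 without 1 h replicate 2. Spry4 was called in all 4 of these fits, and each other gene named here lost its call in at least 1 (without 1 h replicate 1 Etfb 1.46, Egr1 -1.19, Pfdn6 0.71, Polr2l 0.97, Nlrp12 -1.04, Has3 -0.96, Plppr3 -0.77, Tiparp -0.54, Dusp6 -0.46, Spry2 -0.48 and Nfe2l2 -0.28).

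The early and late responses of a line were then set side by side over 14930 genes. Of the 3817 genes called at 1 h in RPB1 and tested at both times, 2370 (62.1%) had the same sign at 12 h. Of those lower at 1 h 1440 of 2101 (68.5%) were negative at 12 h, against 51.9% of all genes, and 333 were called higher. Of those higher at 1 h 930 of 1716 (54.2%) were positive, against 48.1% of all genes. In RPB3 it was 47 of 55 lower genes (85.5%, against 51.3%) and the 1 higher gene. In RPB6 it was 80 of 92 lower genes (87.0%, against 55.5%) and 129 of 145 higher genes (89.0%, against 44.4%). Spry4 was lower at both times in all 3 lines. Across genes Pearson r was 0.266 in RPB1, 0.155 in RPB3 and 0.192 in RPB6, with Spearman rho 0.212, 0.081 and 0.263. Without 1 h replicate 1, r was 0.085 in RPB3 and 0.122 in RPB6, and over genes at 10 CPM or more it was 0.157 in RPB1 and 0.321 in RPB6. The 2 times came from separate libraries with their own controls. Between lines at 1 h, RPB1 and RPB6 shared 223 genes called in the same direction (29.2 for independent lists), RPB1 and RPB3 51 (7.7) and RPB3 and RPB6 16 (0.3).

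Before any IAA the tagged lines already differed from WT. Untreated lines against untreated WT gave a median of 4876.5 genes called over the 12 lines by the edgeR quasi-likelihood test, from 2817 in RPB9 to 9635 in RPB7. These 12 comparisons share the 2 untreated WT libraries, and each line is 1 line, so a difference of the clone cannot be separated from one of the tag. Spry4 was at 5.23 ± 0.614 CPM in untreated WT, 35.5 ± 4.73 CPM in untreated RPB4 and 74.6 ± 2.74 CPM in untreated RPB2. Chac1 was at 132 ± 3.16 CPM in untreated RPB7 and 24.9 ± 0.315 CPM in untreated WT. Without untreated replicate 2 of WT the median count was 2902.5.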

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

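Both tests of the Cyp1a1 pattern, and the tests of gene lists between pairs of lines, were chosen only after the result was seen.

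Responses of 2 lines differed by a test of the difference itself, which cannot separate subunit from clone. The number of genes whose response differed was 4397 for RPB4 against RPB7, 2213 for RPB3 against RPB11, 11227 for RPB1 against RPB2 and 6836 for RPB9 against RPB1 (edgeR quasi-likelihood test). Between RPB1 and RPB2 the log2 fold changes of p53 targets differed by a median of 2.98 (camera, adjusted p = 2.81e-07). Those of short-lived mRNAs differed by 3.56 (camera, adjusted p = 2.03e-13). In both lists the median was positive in RPB1 and negative in RPB2.

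Cyp1a1 rose after IAA in WT and in each degron line, and in 6 degron lines, RPB4 narrowly, its change differed from that of WT by test, by 3.12 ± 1.04 in RPB5. Scaling is argued against in RPB5 only (2.67 scaled to mitochondrial mRNAs). The others of the 6, chosen for differing, had 3 or fewer untreated counts. Earlier forms of the test were dropped, for no untreated count in RPB4 and for scaling that moved nothing in RPB12. WT libraries that had received no IAA are argued against by the genes called in the same direction in WT and RPB4, 87 against 3.1 for independent lists, a ratio of 28.1. IAA acting as a ligand of the aryl hydrocarbon receptor is an untested hypothesis for the rise itself. The difference between WT and the degron lines stays open, since tag, clone and any OsTir1 difference are not separated.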

How the results depend on the processing

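Scaling to total counts and to mitochondrial mRNAs, the latter also without 1 library of RPB3, and the left-out libraries for correlations were chosen only after the results were seen. Counts of called genes moved by over 1.5 times as follows, and the cause was not tested unless the setting itself gives it. Requiring an absolute log2 fold change of 1 or more, which removes genes by construction, left 68 in WT at 12 h, 6975 in RPB1 at 12 h, 3260 in RPB3 at 12 h, 108 in RPB4 at 12 h, 5514 in RPB5 at 12 h, 2487 in RPB7 at 12 h, 6575 in RPB8 at 12 h, 1896 in RPB9 at 12 h, 2665 in RPB10 at 12 h, 1043 in RPB11 at 12 h, 230 in RPB12 at 12 h, 699 in RPB1 at 1 h, 24 in RPB3 at 1 h, 25 in RPB6 at 1 h, 1825 in RPB4 against RPB7 at 12 h, 677 in RPB3 against RPB11 at 12 h, 3505 in RPB9 against RPB1 at 12 h and 1287.5 in untreated lines against WT. Fits on the libraries of a comparison alone, with fewer residual degrees of freedom, gave 1060 in WT at 12 h, 667 in RPB4 at 12 h, 3909 in RPB7 at 12 h, 1890 in RPB11 at 12 h, 2021 in RPB12 at 12 h, 17 in RPB3 at 1 h, 488 in RPB6 at 1 h, 2839 in RPB4 against RPB7 at 12 h and 1056 in RPB3 against RPB11 at 12 h. Subtracting the WT change left 5056 in RPB3 at 12 h, 51 in RPB4 at 12 h, 4519 in RPB7 at 12 h, 3224 in RPB9 at 12 h, 4589 in RPB10 at 12 h, 2024 in RPB11 at 12 h and 95 in RPB12 at 12 h. Scaling to mitochondrial mRNAs gave 7 in WT at 12 h, 30 in RPB4 at 12 h, 4657 in RPB7 at 12 h, 1995 in RPB9 at 12 h, 3382 in RPB10 at 12 h, 497 in RPB11 at 12 h, 78 in RPB12 at 12 h, 1241 in RPB1 at 1 h, 8 in RPB3 at 1 h, 1 in RPB6 at 1 h, 2001 in RPB4 against RPB7 at 12 h, 290 in RPB3 against RPB11 at 12 h, 3294 in RPB9 against RPB1 at 12 h and 1054 in untreated lines against WT. With that scaling and IAA replicate 2 of RPB3 left out it was 14114 in RPB3 at 12 h and 12394 in RPB3 against RPB11 at 12 h, and with IAA replicate 1 left out 6508 and 2329. Without the filter the count was 166 in RPB3 at 1 h and 815 in RPB6 at 1 h. DESeq2 gave 2525 in RPB1 at 1 h. RLE size factors, total counts and all 64 libraries in one fit moved no count by that much. Scaling to fly counts was not run, for the counts or for shared against specific subunits, because 0 fly genes were in the table used. Camera with an estimated correlation called 48 lists and fry 229, against 125. For camera, leaving out 1 library gave 122 to 129.

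Libraries with the same number did not deviate together (correlations -0.339 to 0.189 over 16 lines and times, 3 of them over 0.1), so the samples share only a number. With the replicate block the count was 180 in WT at 12 h and 683 in RPB6 at 1 h, and no other count moved by over 1.5 times.

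With 1 library left out, the lone library of its group is assumed to vary like the other groups. Counts then ran from 92 to 112 in WT at 12 h, 140 to 193 in RPB4 at 12 h, 2711 to 3597 in RPB11 at 12 h, 397 to 460 in RPB12 at 12 h, 1380 to 2710 in RPB1 at 1 h, 29 to 238 in RPB3 at 1 h, 2 to 425 in RPB6 at 1 h, 1365 to 2060 in RPB3 against RPB11 at 12 h and 2902.5 to 4876.5 in untreated lines against WT. Correlations ran from 0.177 to 0.225 for all pairs, -0.031 to 0.046 for RPB4 with RPB7, 0.412 to 0.504 for RPB3 with RPB11, 0.137 to 0.239 for RPB1 with RPB2, 0.204 to 0.286 for 1 h against 12 h in RPB1, 0.085 to 0.175 for 1 h against 12 h in RPB3 and 0.122 to 0.196 for 1 h against 12 h in RPB6. That of RPB4 with RPB7, 0.000 with all libraries, changed sign in 4 of its 8 cases. The permutation test of shared subunits passed 0 lists under each of its alternatives.

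Correlations that moved by over 1 SD of the values with a library left out were, with Spearman, 0.195 in all pairs, 0.557 in RPB3 with RPB11, 0.14 in RPB1 with RPB2, 0.212 in 1 h against 12 h in RPB1, 0.081 in 1 h against 12 h in RPB3 and 0.263 in 1 h against 12 h in RPB6. Over genes at 10 CPM or more they were 0.295 in all pairs, 0.063 in RPB4 with RPB7, 0.733 in RPB3 with RPB11, 0.045 in RPB1 with RPB2, 0.157 in 1 h against 12 h in RPB1, 0.125 in 1 h against 12 h in RPB3 and 0.321 in 1 h against 12 h in RPB6. Minus the WT response they were 0.392 in all pairs, 0.31 in RPB4 with RPB7, 0.626 in RPB3 with RPB11 and 0.293 in RPB1 with RPB2, where simulated lines without an effect, which share the WT libraries, gave 0.46. Of 238 values of named genes 231 were called, and 205 of these stayed called in each planned fit and with each library left out, while 26 lost their call in at least 1. A minimum fold change and the added scalings are not in these counts. Polr2k in RPB12, not called, ran from -0.49 to 0.14 with an IAA library left out and so changed sign without IAA replicate 2. At 3399838 counts in the shallowest library, 1 CPM is about 3 counts, and 55.2% of simulated doublings were recovered in RPB4.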

Other observations

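The tests of genomic DNA, of run-on as the whole cause and of gene length in RPB6, and the sums over receptor genes, were chosen only after the result was seen. Conditions were added to the tests of run-on reads and of fragment size or RNA quality after their values were seen.

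Genes of odour and pheromone receptors, 1464 in number, were summed without a test, in CPM of all counts (n = 2). The sum was 17.8 ± 2.64 CPM in untreated RPB1 and 144 ± 12.4 CPM after 12 h of IAA. In RPB5 it was 23.5 ± 3.75 and 86.1 ± 11.7 CPM, and in RPB3 12.6 ± 0.21 and 55.6 ± 9.82 CPM. In WT it was 16.3 ± 2.36 and 21.1 ± 0.39 CPM. RPB2 had 16.4 ± 0.34 and 14.1 ± 0.78 CPM, and RPB6 18.5 ± 2.4 and 10.6 ± 2.16 CPM. The 4373 silent genes summed after IAA to 244 ± 19.7 CPM in RPB5, 159 ± 5.24 in RPB8, 111 ± 16.6 in RPB3, 70.3 ± 6.05 in RPB2, 22.7 ± 4.78 in RPB6 and 12.4 ± 0.16 in RPB4. The responses of RPB9 and WT shared 168 genes called in the same direction, against 51.4 for independent lists, and 27 in the opposite one.

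Silent genes gained counts in RPB1 after 12 h of IAA. Genomic DNA as the whole cause is argued against. No count in either library was found for 71.8% of silent genes, where an even spread along exonic length gives 33.8%. Run-on over up to 20 kb from an active gene (10 CPM or more) is argued against as the whole cause. Farther away lay 68.3% (exact 95% interval 63.3 to 73.0) of the 375 genes with 5 or more counts and 3925 of 4373 silent genes. Such reads may still add a part: 33.6% of silent genes downstream of an active gene within 20 kb on the same strand had 5 or more counts, against 6.5% far from any, a ratio of 5.157, but genes upstream of one reached 25.4%. Longer run-on and transcription of silent genes on loss of RPB1 stay open, as untested hypotheses.

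Short genes lay higher at 1 h in RPB1 (Spearman rho -0.202 with exonic length across genes) and in RPB6 (-0.183). The 2 libraries of a group in RPB1 differed along length by at most 0.057, which met the bound set beforehand for excluding fragment size or RNA quality. That bound was too narrow, since the 2 libraries at 1 h differed by 0.323 in RPB3 and -0.184 in RPB6, so this explanation stays open. Exonic length, with transcript length untested, is argued against as the whole cause of the rise of ribosomal protein and oxidative phosphorylation genes. With its trend removed their medians were 0.16 (from 0.27) and 0.20 (from 0.33) in RPB1. In RPB6 they were 0.16 (from 0.23) and 0.20 (from 0.28). A change of mRNA levels within 1 h stays open, untested.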
